A study of Danio rerio with 15 samples.

How the data were processed

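Total RNA was extracted from zebrafish larvae of the TL strain at 4 days after fertilization and made into NEBNext Ultra II libraries, per the labels' protocols. Larvae were raised with a pigment synthesis inhibitor. The 15 libraries form 5 groups of 3: uninjected wild type, zymosan-injected wild type, uninjected and zymosan-injected triple mutants of tfeb, tfe3a and tfe3b, and uninjected rraga mutants. Groups and replicate numbers were taken from the labels, which call the samples biological replicates. The p-values measure the spread between these samples.

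The authors deposited 3 tables, each with 6 libraries. Per the submitters' processing notes, reads were aligned to GRCz11 with HISAT2 2.0.5, StringTie 1.3.3b was used, and reads per gene were counted with featureCounts 1.5.0. Whether strand was used in counting is not given, so reads of overlapping and antisense genes cannot be told apart, and near-identical copies (crystallins, globins, opsins, heat shock genes) may share reads. Each deposited table holds raw counts per gene, a signal that is the count divided by a size factor per library, and FPKM values, all made by the authors. Only the deposited counts were used for tests. The deposited signal and FPKM values are already scaled, so count models do not apply to them, and they were not used here. Each table lists the genes with a total of at least 2 counts over its 6 libraries. A gene missing from a table therefore has a total of at most 1 there and was set to 0. The uninjected wild-type counts stand in 2 of the tables and were identical for the 22631 genes listed in both. The tables together hold 24609 genes, of which 22086 are in all 3. Gene symbols, positions and identifiers came from the tables and a table of names, in which 23008 identifiers were found. Of 18 symbols that had turned into dates, 16 were restored. Coordinates are those of the deposited tables, on GRCz11, and no genome was used.

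Library totals ran from 12314113 to 17566540 counts. The mitochondrial genome took between 7.99% and 14.01% of counts, and the 10 most abundant genes between 14.9% and 20.45%. Replicates were checked for duplicates: among the 15 pairs within groups, 0 were identical, and chi-square per degree of freedom of their counts lay between 3.94 and 26.39, above sampling noise in every pair. Reads carry no molecular identifiers, so counting intervals and floors cover counting error only.

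Counts were analysed with edgeR 4.0.16 in R 4.3.3. Genes were kept by filterByExpr, which left 19006, and scaled with TMM, whose factors lay between 0.85 and 1.187. A single quasi-likelihood model with a mean per group was fitted to all 15 libraries (common biological coefficient of variation 0.165), and 7 contrasts were tested: triple mutant against wild type without and with zymosan, zymosan against uninjected in each of these genotypes, the interaction of zymosan and genotype, and rraga mutants against uninjected wild type and against uninjected triple mutants. A gene is said to have changed at a Benjamini-Hochberg adjusted p under 0.05 within a contrast, and each adjusted p given for a gene comes from this edgeR test. Standard errors of log2 fold changes were derived from the quasi-likelihood F statistic. Levels are CPM, counts scaled by each library's TMM-adjusted size, as mean ± SD over 3 libraries. Where a group held 0 counts of a gene, a fold is a lower bound against a floor of 3 counts over the group. Where it held 1 to 3, the ratio is given with its 95% counting interval, since a fitted fold change of such a gene is no bound.

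A total of 33 gene lists were written down before the data were examined, along with the groups, tests, rule for named genes and all alternatives except those said to be chosen later. They cover lysosomal hydrolases, lysosomal membrane and v-ATPase (and all 3 together), autophagy, the Rag, Ragulator and mTORC1 pathway, MiT/TFE factors, microglia and macrophages, neutrophils, the inflammatory response, acute phase and complement, the interferon response, cholesterol synthesis, lipid handling and fatty acid oxidation, the integrated stress response, endoplasmic reticulum chaperones, p53 targets, cell cycle, heat shock and oxidative stress, the circadian clock, ribosomal proteins, mitochondrially encoded genes, and markers of myelin, pigment cells, neurons, radial glia, photoreceptors, lens, skeletal muscle, erythrocytes, hepatocytes, exocrine pancreas and enterocytes. Lists were tested with camera in limma 3.58.1 with a preset correlation of 0.01, adjusted over the 33 lists of a contrast, and again with a correlation estimated per list and with fry. Of 231 list tests, 91 passed, of which 34 also passed with an estimated correlation. A list's median, mean and test had the same sign in all that passed and differed in 30 that did not. Counts of members are given over all tested genes and adjusted over the list alone.

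Named genes are the 4 targeted genes, the 5 largest increases and decreases per contrast among changed genes with a mean log2 CPM above 1 and no overlap between the groups' libraries (this last condition not for the interaction; unnamed and clone symbols left out), and up to 4 members with the smallest p per list. The fitting steps were tested on simulated counts with known changes: 2-fold and 4-fold changes were recovered for 59% and 82% of genes in the contrast of uninjected triple mutants and wild type, 57% and 83% for rraga mutants, and 37% and 76% for the interaction. Alternatives were DESeq2 1.42.0, DESeq2's size factors, other filters on low counts, a fit of each contrast's groups alone, the replicate number as a block, leaving out each library, and leaving out the chromosomes of the targeted genes.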

Results

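RNA was sequenced from 15 samples of zebrafish larvae at 4 days after fertilization, and reads per gene were compared between 5 groups of 3 samples each. The groups were uninjected wild type, wild type injected with zymosan, uninjected and zymosan-injected larvae mutant in tfeb, tfe3a and tfe3b (called triple mutants here), and uninjected rraga mutants. Zymosan is a yeast cell wall preparation that phagocytes take up and that sets off inflammation. Tfeb and Tfe3 are transcription factors that switch on genes for lysosomes, the digestive compartments of the cell. The gene rraga encodes RagA, a GTPase that holds these factors in the cytoplasm when nutrients are plentiful. Libraries held between 12314113 and 17566540 counts, and 19006 genes were tested. On the leading axis of a plot of distances between libraries, which held 36.7% of the variation, the 6 triple-mutant libraries lay apart from the other 9. On the second axis, which held 12.3%, the 3 rraga libraries lay apart.

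The targeted genes were examined first, because they check the labels. Transcript of tfe3b (ENSDARG00000019457, chromosome 11, 25504215 to 25519837 on GRCz11) stood at 1.69 ± 0.481 CPM (mean ± SD, n = 3) in uninjected wild type and 0.108 ± 0.0317 CPM in uninjected triple mutants. The difference passed edgeR's quasi-likelihood test (log2 fold change -3.84 ± 0.87 (SE), adjusted p = 0.00455). Under zymosan the gene stood at 2.85 ± 0.582 CPM in wild type and 0.309 ± 0.478 CPM in triple mutants (-3.17 ± 0.74, adjusted p = 0.00556). Of its 13 counts in the latter group, 12 came from a single library. Transcript of tfeb (ENSDARG00000010794, chromosome 11, 22287954 to 22361306) stood at 9.06 ± 0.277 CPM in uninjected wild type and 9.05 ± 2.47 CPM in uninjected triple mutants (0.01 ± 0.20, adjusted p = 0.994). Transcript of tfe3a (ENSDARG00000098903, chromosome 8, 7778770 to 7809451) stood at 3.09 ± 1.24 and 2.31 ± 0.962 CPM in these groups (-0.42 ± 0.38, adjusted p = 0.581). In rraga mutants, rraga itself (ENSDARG00000104149, chromosome 14, 14027427 to 14094406) was higher, at 26 ± 0.928 CPM against 14.7 ± 2.72 CPM in wild type (0.83 ± 0.14, adjusted p = 0.000338). The kind of lesion each line carries is not given in the sources used here. A transcript level at or above that of wild type therefore neither checks nor contradicts a label.

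**Figure D1:**
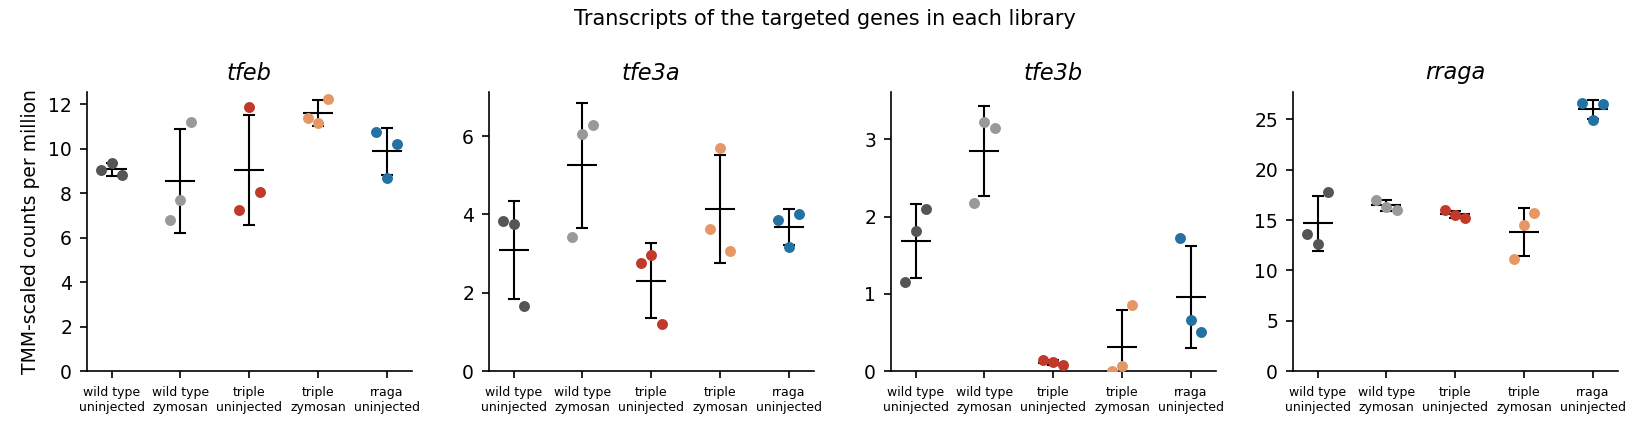
Transcript levels of tfeb, tfe3a, tfe3b and rraga in CPM (y axis) in the 5 groups (x axis), with libraries as points and means with their SD as bars (n = 3). Levels of tfe3b lie at 0.108 in uninjected triple mutants against 1.69 in uninjected wild type.

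The first comparison asked which lysosomal genes differ between uninjected triple mutants and uninjected wild type. Genes for lysosomal enzymes were lower in the mutants. Of the hydrolases, 14 of 68 were lower and 1 higher (23 and 2 adjusted over the list alone). The cathepsin B gene ctsba (ENSDARG00000055120, chromosome 17, 32622931 to 32631514) had 0 counts in the 3 mutant libraries and 2027 in wild type. That is at least 766-fold lower against a floor of 3 counts over the group. Such absence was not confined to lysosomal genes: tgm2l had 0 counts in mutants against 266 in wild type. The reverse held for znf1156, with 0 counts in wild type against 307 in mutants. The lysosomal nuclease gene dnase2 stood at 2.09 ± 0.256 CPM in mutants and 8.96 ± 1.8 CPM in wild type (log2 fold change -2.09 ± 0.23). For ctsk, which encodes cathepsin K, the levels were 6.86 ± 1.05 and 18.9 ± 1.92 CPM (-1.47 ± 0.18). For ctsa, which encodes the protective protein cathepsin A, they were 12.8 ± 0.696 and 25 ± 2.59 CPM (-0.96 ± 0.13). The hydrolases passed as a list (camera, adjusted p = 1.59e-05, or adjusted p = 0.0346 with an estimated correlation), with a median log2 fold change of -0.30. At the preset correlation the list also passed without ctsba, an exclusion chosen after seeing the data.

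Other parts of the lysosome went both ways. Among lysosomal membrane genes, 5 of 54 were lower and 1 higher (5 and 1 adjusted over the list alone), and the list did not pass (adjusted p = 0.694). The sorting receptor gene sort1a (-3.52 ± 0.55) and the lysolipid transporter gene spns1 (-0.77 ± 0.15) were lower. Of the genes for the v-ATPase, the pump that acidifies lysosomes, 3 of 26 were higher and 3 lower (4 and 5 adjusted over the list alone, adjusted p = 0.627). The catalytic subunit gene atp6v1ab was higher, at 45 ± 2.44 against 9.19 ± 0.464 CPM (2.29 ± 0.20). Its partner atp6v1g1 was lower, at 31.4 ± 6.53 against 88.7 ± 4.17 CPM (-1.50 ± 0.13). Of all lysosomal genes together, 22 of 148 were lower and 5 higher (34 and 8 adjusted over the list alone). That list passed as lower (adjusted p = 0.00824, or adjusted p = 0.386 with an estimated correlation). Of autophagy genes, 1 of 56 were higher and 0 lower (1 and 0 adjusted over the list alone, adjusted p = 0.369). In the Rag, Ragulator and mTORC1 pathway, 3 of 39 were higher and 2 lower (4 and 3 adjusted over the list alone, adjusted p = 0.864), and mlst8, for a subunit of the mTOR complexes, was lower (-5.63 ± 0.58). Among the 8 measured MiT/TFE factors tfe3b alone changed (adjusted p = 0.726).

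Microglia, the macrophages of the brain, digest what they engulf in lysosomes. Of the microglia and macrophage genes, 6 of 41 were lower and 0 higher in triple mutants (7 and 0 adjusted over the list alone). The granulin gene grn1 stood at 1.65 ± 0.349 against 6.9 ± 1.56 CPM (-2.07 ± 0.31) and the apolipoprotein E gene apoeb at 178 ± 18.1 against 242 ± 8.29 CPM (-0.45 ± 0.09). The tetraspanin gene cd9b was lower too (-0.80 ± 0.13). The list did not pass camera (adjusted p = 0.0963), while fry, which asks only whether members move together, gave adjusted p = 0.00157. Of its members, 2 are also in the lysosomal lists. Of inflammatory genes, 7 of 62 were lower and 2 higher (9 and 3 adjusted over the list alone, adjusted p = 0.369), and those lower included the AP-1 genes fosab (-1.53 ± 0.14) and junbb (-0.75 ± 0.14).

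Several other lists passed at the preset correlation of 0.01, but none of them with an estimated correlation. The estimate was 0.383 for lens and 0.946 for mitochondrially encoded genes. Of the lens crystallins and lens membrane genes, 20 of 38 were lower and 2 higher (23 and 2 adjusted over the list alone), and the list passed (adjusted p = 5.52e-05, or adjusted p = 0.829 with an estimated correlation). The beaded filament genes BFSP1 (-1.72 ± 0.15) and bfsp2 (-0.83 ± 0.10) were lower. Transcript of the lens water channel gene mipa was instead higher, at 65.9 ± 6.49 against 0.926 ± 0.154 CPM. In lipid handling and fatty acid oxidation, 8 of 56 were lower and 0 higher (8 and 1 adjusted over the list alone), which passed as lower (adjusted p = 0.0311, or adjusted p = 0.711 with an estimated correlation). Leading it were hadhaa (-1.49 ± 0.11) and HADHB (-0.66 ± 0.09), which encode the mitochondrial trifunctional protein. Mitochondrially encoded genes passed as lower (1 of 13 lower and 0 higher, adjusted p = 0.00824, or adjusted p = 0.829 with an estimated correlation), as did skeletal muscle genes (8 of 45 lower and 2 higher, adjusted p = 0.016, or adjusted p = 0.829 with an estimated correlation) and ribosomal proteins (3 of 80 lower and 2 higher, adjusted p = 0.0216, or adjusted p = 0.842 with an estimated correlation). Exocrine pancreas genes passed as higher (3 of 21 higher and 1 lower, adjusted p = 0.016, or adjusted p = 0.829 with an estimated correlation). Of photoreceptor genes, 10 of 36 were lower and 2 higher, without passing (adjusted p = 0.077).

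Across all genes, 1856 changed between uninjected triple mutants and wild type, 746 higher and 1110 lower. Among changed genes with an established symbol, a mean log2 CPM above 1 and no overlap between the groups' libraries, the largest increase was in lta4h (leukotriene A4 hydrolase, chromosome 4, 7653607 to 7673165), from 0.211 ± 0.117 to 26 ± 3.74 CPM (log2 fold change 6.81 ± 0.39). The chemokine gene cxcl12b followed, from 0.279 ± 0.308 to 27.4 ± 3.4 CPM (6.72 ± 0.37). Then came ldb2b, for a LIM domain binding protein (6.67 ± 0.48), the cone transducin gene gngt2a (6.12 ± 0.40) and mipa (6.12 ± 0.23). Within these limits, the largest decrease after ctsba was in the actin gene actc1c, with 2 counts against 1135 (a ratio of 643, 95% counting interval 178 to 5320). The fatty acid elongation gene hacd3 had 1 count against 431 (489, 87.2 to 19300). The gene shisa4 had 2 against 698 (396, 109 to 3270) and the glutamate receptor gene grm2b 2 against 639 (362, 99.9 to 3000). Many large differences were neighbours on a chromosome. Of 399 genes that changed over 4-fold, 63.2% had another within 0.5 Mb, against at most 39.3% in 1000 shuffles. Between 15 and 20 Mb of chromosome 18, 23 of 82 tested genes were over 4-fold lower. Without the 5 Mb windows dense in such changes, a restriction chosen after seeing the data, 1324 genes changed. The gene lists were not tested without these windows.

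**Figure D2:**
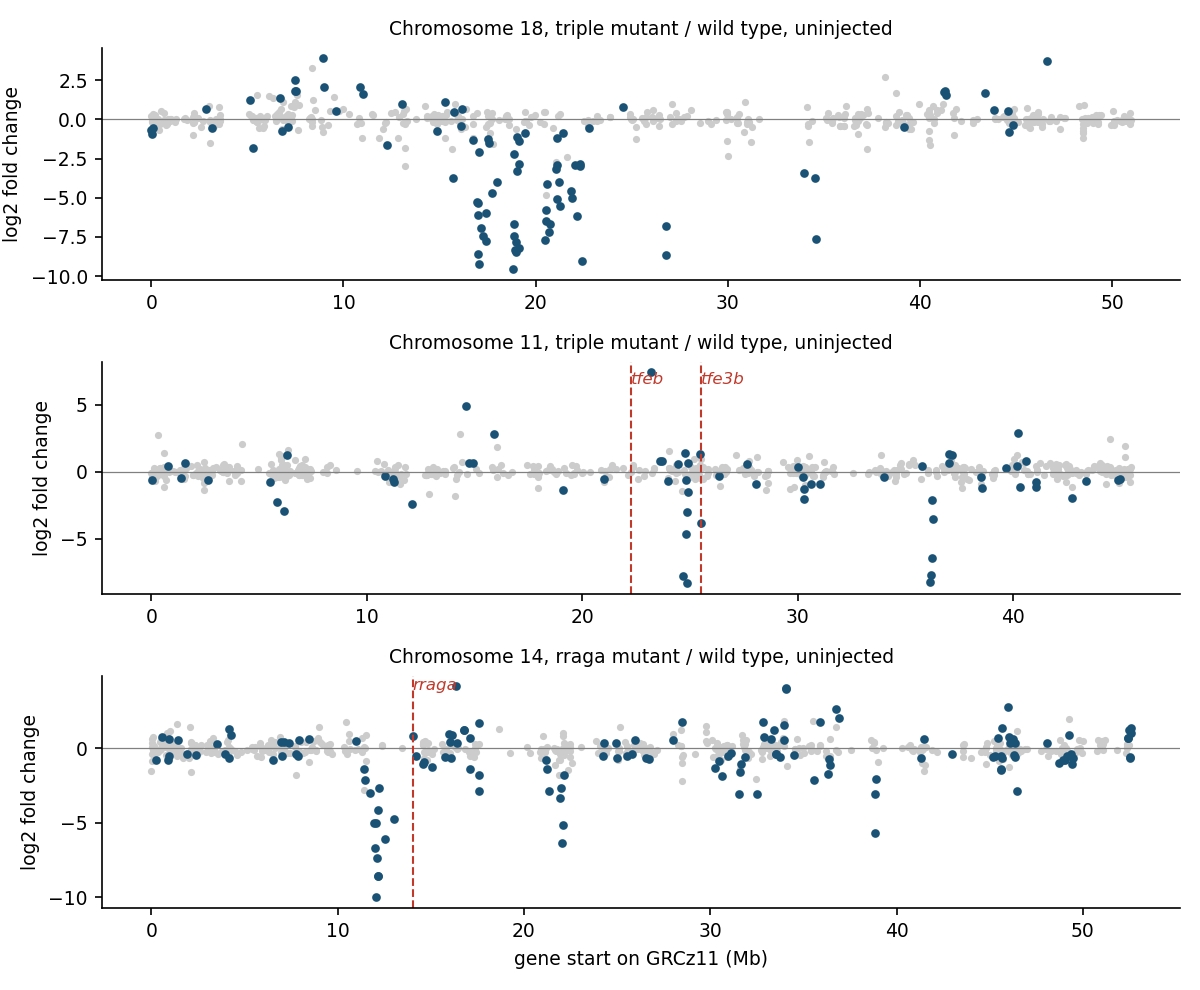
Log2 fold change of each tested gene (y axis) by its start on GRCz11 in Mb (x axis), for triple mutants against wild type on chromosomes 18 and 11 and rraga mutants against wild type on chromosome 14, with changed genes in blue, others in grey, and dashed red lines at tfeb, tfe3b and rraga. Large decreases cluster between 15 and 25 Mb of chromosome 18 and between 10 and 15 Mb of chromosome 14.

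The same comparison was made under zymosan. Again lysosomal hydrolases were lower in triple mutants, where 11 of 68 were lower and 0 higher (11 and 0 adjusted over the list alone), and the list passed (camera, adjusted p = 0.00124, or adjusted p = 0.0743 with an estimated correlation). Counts of ctsba were 0 in mutants and 2757 in wild type, at least 882-fold lower. Levels of dnase2 were 2.25 ± 0.555 against 10.4 ± 0.547 CPM (log2 fold change -2.20 ± 0.23), and ctsk was lower as well (-1.45 ± 0.18). The hexosaminidase gene hexb stood at 33.5 ± 1.82 against 57.5 ± 7.98 CPM (-0.78 ± 0.11). Over all lysosomal genes, 20 of 148 were lower and 5 higher (20 and 6 adjusted over the list alone), and the list passed (adjusted p = 0.0182, or adjusted p = 0.471 with an estimated correlation). This call ended without triple-mutant zymosan replicate 2 (adjusted p = 0.0704) and without ctsba (adjusted p = 0.0679, an exclusion chosen after seeing the data). Microglia and macrophage genes did not pass as a list (adjusted p = 0.323), and grn1 was lower again (-2.24 ± 0.31).

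Photoreceptor genes were lower in zymosan-injected triple mutants than in zymosan-injected wild type. Of the list, 24 of 36 were lower and 1 higher (27 and 2 adjusted over the list alone), and it passed (adjusted p = 2.88e-28, or adjusted p = 0.0743 with an estimated correlation). The ultraviolet opsin gene opn1sw1 stood at 566 ± 25.4 against 2924 ± 722 CPM (log2 fold change -2.37 ± 0.16) and the blue opsin gene opn1sw2 at 26.4 ± 2.83 against 103 ± 21.1 CPM (-1.96 ± 0.16). The rod transducin gene gnat1 was lower too (-1.36 ± 0.11). Lens genes passed as lower (18 of 38 lower and 2 higher, adjusted p = 0.00464, or adjusted p = 0.831 with an estimated correlation), as did mitochondrially encoded genes (5 of 13 lower and 0 higher, adjusted p = 0.00273, or adjusted p = 0.831 with an estimated correlation). In zymosan-injected wild type the mitochondrial genome took 14.01% and 13.47% of counts in replicates 1 and 2 and 9.4% in replicate 3, against 9.13% to 10.66% in the triple mutants. Replicate 3 also differed most from its group in counts overall (chi-square per degree of freedom 26.39 and 24.28, against 5.68 between the others). Without replicate 1 the mitochondrially encoded list gave adjusted p = 0.0613, and without replicate 3 adjusted p = 2.12e-09. Enterocyte genes (8 of 39 lower and 2 higher, adjusted p = 0.0182, or adjusted p = 0.831 with an estimated correlation) and ribosomal proteins (3 of 80 lower and 3 higher, adjusted p = 0.0143, or adjusted p = 0.831 with an estimated correlation) passed as lower. Acute phase and complement genes passed as higher (8 of 47 higher and 2 lower, adjusted p = 0.02, or adjusted p = 0.831 with an estimated correlation), with the complement gene c3b.1 at 4.64 ± 0.55. Erythrocyte genes, including the embryonic beta globin gene hbbe1.1 (1.03 ± 0.16), were higher (7 of 23 higher and 1 lower, adjusted p = 0.00316, or adjusted p = 0.471 with an estimated correlation), with the limit that near-identical globin copies can share reads.

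In all, 2255 genes changed between the genotypes under zymosan, 990 higher and 1265 lower. Within the same limits on symbol, mean CPM and overlap, the largest increase was in cxcl12b, which had 0 counts in zymosan-injected wild type against 973 in mutants, at least 338-fold higher. Next were ldb2b (6.04 ± 0.45), the prostaglandin E synthase gene ptges3a (5.82 ± 0.28), mipa (5.70 ± 0.21) and lta4h (5.56 ± 0.34). After ctsba the largest decreases within these limits were in shisa4 (0 against 719 counts, at least 230-fold lower) and actc1c (-7.82 ± 0.41). The carboxylesterase gene ces2 (-7.43 ± 0.38) and pou3f2b, for a neural POU transcription factor (-7.33 ± 0.35), followed. Of the genes higher in uninjected mutants, 472 were also higher under zymosan, where independent lists would share 38.9. Lower under both conditions were 734, where independent lists would share 73.9, and 3 had opposite calls. The genotype effects with and without zymosan correlated across genes (Pearson r = 0.779, Spearman rho = 0.538), with the limit that genes are not independent replicates.

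The zymosan response was then examined within each genotype. No group was injected without zymosan, so effects of injection and handling cannot be told apart from those of zymosan in these comparisons. In wild type, inflammatory genes rose. Of these, 26 of 62 rose and 0 fell (30 and 0 adjusted over the list alone), and the list passed (camera, adjusted p = 9.67e-24, or adjusted p = 2.02e-05 with an estimated correlation). The cytokine signalling inhibitor gene socs3b went from 16.1 ± 1.35 to 104 ± 12.2 CPM (log2 fold change 2.68 ± 0.13). The transcription factor gene cebpb went from 31.3 ± 4.64 to 100 ± 6.8 CPM (1.68 ± 0.12), and the AP-1 gene junba rose as well (1.84 ± 0.12). Of liver acute phase and complement genes, 6 of 47 rose and 0 fell (7 and 0 adjusted over the list alone, adjusted p = 2.14e-05, or adjusted p = 0.354 with an estimated correlation). The fibrinogen gene fga went from 101 ± 9.98 to 327 ± 22.1 CPM (1.69 ± 0.11), with fgb (1.66 ± 0.13) and the hepcidin gene hamp (2.44 ± 0.43). Neutrophil genes went both ways and did not pass as a list (adjusted p = 0.237). The gelatinase gene mmp9 rose from 1.98 ± 0.355 to 12 ± 3.6 CPM (2.59 ± 0.28), while mpx, for myeloperoxidase, went from 3.69 ± 0.22 to 0.554 ± 0.153 CPM (-2.73 ± 0.35). The granule gene npsn fell too (-1.64 ± 0.23).

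Lysosomal genes did not move as a list with zymosan in wild type. Of these, 9 of 148 rose and 7 fell (9 and 8 adjusted over the list alone, adjusted p = 0.603), with a median log2 fold change of 0.07. The hydrolases went both ways (adjusted p = 0.953). Cathepsin L transcript (ctsla) rose from 227 ± 10.7 to 310 ± 36.4 CPM (0.45 ± 0.10), and hexb fell from 77.5 ± 5.13 to 57.5 ± 7.98 CPM (-0.43 ± 0.11). Lysosomal membrane genes (adjusted p = 0.846), v-ATPase genes (adjusted p = 0.141) and autophagy genes (adjusted p = 0.132) did not pass. Of microglia and macrophage genes, 4 of 41 rose and 0 fell (4 and 0 adjusted over the list alone, adjusted p = 0.725).

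In camera at the preset correlation, circadian clock genes had the smallest p of any list in wild type. Of these, 22 of 36 rose and 0 fell (27 and 1 adjusted over the list alone), and the list passed (adjusted p = 3.7e-52, or adjusted p = 2.02e-05 with an estimated correlation). The light-inducible period gene per2 rose from 9.56 ± 2.17 to 225 ± 7.43 CPM (log2 fold change 4.55 ± 0.42). The cryptochrome family gene cry5 rose from 1.29 ± 0.795 to 28.1 ± 1.58 CPM (4.50 ± 0.36) and lonrf1l from 6.25 ± 1.06 to 191 ± 6.85 CPM (4.95 ± 0.23). With the dioxin-inducible gene cyp1a (5.09 ± 0.54) and wdr76 (4.62 ± 0.65), these were the 5 largest increases within the same limits on symbol, mean CPM and overlap. The largest decreases within them were in the collagen chaperone gene serpinh1b (-3.05 ± 0.32), mpx, the retinal homeobox gene rx2 (-2.31 ± 0.28), the activity-dependent gene npas4a (-2.19 ± 0.28) and rps6kal (-2.19 ± 0.48). Per the labels, injected larvae and rraga mutants were examined under a confocal microscope before freezing. Whether uninjected wild-type larvae were is not given in the sources used here. Of the 22 clock genes that rose, 10 were higher and 1 lower in rraga mutants than in uninjected triple mutants, a comparison that shares no library with this one. The share higher there was 45.5%, against 13.9% of all tested genes.

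**Figure D3:**
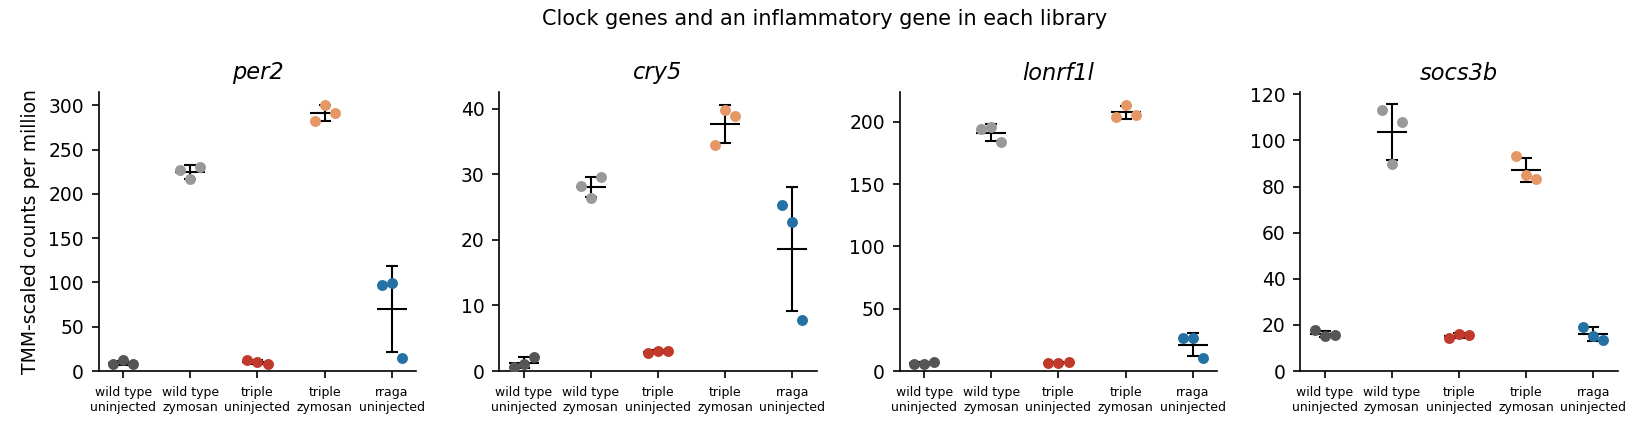
Transcript levels of per2, cry5, lonrf1l and socs3b in CPM (y axis) in the 5 groups (x axis), with libraries as points and means with their SD as bars (n = 3). Levels of per2 are 9.56 ± 2.17 in uninjected wild type, 225 ± 7.43 in zymosan-injected wild type and widely spread in rraga mutants (70.4 ± 48.6), while socs3b is high in the zymosan groups alone.

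Further groups rose with zymosan in wild type. Among p53 targets, 7 of 17 rose and 0 fell (adjusted p = 3.15e-06, or adjusted p = 0.0167 with an estimated correlation), with the stress sensor gene sesn1 at 1.13 ± 0.10. In the integrated stress response, 9 of 47 rose and 2 fell (adjusted p = 2.45e-06, or adjusted p = 0.0194 with an estimated correlation), with the phosphatase regulator gene ppp1r15a at 0.98 ± 0.11. In lipid handling and fatty acid oxidation, 12 of 56 rose and 1 fell (adjusted p = 1.02e-05, or adjusted p = 0.0319 with an estimated correlation), with the pyruvate dehydrogenase kinase gene pdk2b at 3.45 ± 0.22. Of interferon response genes, 4 of 20 rose and 0 fell (adjusted p = 0.00427, or adjusted p = 0.0319 with an estimated correlation), with irf9 at 1.59 ± 0.19. Cell cycle genes went down, and 14 of 40 fell and 1 rose (adjusted p = 7.92e-07, or adjusted p = 0.00647 with an estimated correlation), with the replication helicase gene mcm2 at -0.69 ± 0.10. Cholesterol synthesis (7 of 33 up and 0 down, adjusted p = 0.000148, or adjusted p = 0.0745 with an estimated correlation) and heat shock and oxidative stress genes (15 of 44 up and 2 down, adjusted p = 1.45e-05, or adjusted p = 0.0695 with an estimated correlation) passed as higher. Enterocyte (13 of 39 up and 0 down, adjusted p = 5.6e-08, or adjusted p = 0.146 with an estimated correlation) and hepatocyte genes (4 of 33 up and 0 down, adjusted p = 1.45e-05, or adjusted p = 0.431 with an estimated correlation) did so too. Lens (3 of 38 up and 0 down, adjusted p = 0.00121, or adjusted p = 0.569 with an estimated correlation) and radial glia genes (3 of 21 up and 1 down, adjusted p = 0.0248, or adjusted p = 0.169 with an estimated correlation) completed the lists that passed. Endoplasmic reticulum chaperones (adjusted p = 0.343), photoreceptors (adjusted p = 0.109) and pigment cell genes (adjusted p = 0.433) did not pass. In all, 1881 genes changed, 1153 up and 728 down.

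In triple mutants, inflammatory genes were higher after zymosan injection as well, with the same limit on what injection itself does. Of these, 26 of 62 rose and 0 fell (33 and 1 adjusted over the list alone), and the list passed (camera, adjusted p = 7.76e-25, or adjusted p = 3e-05 with an estimated correlation). Levels of socs3b went from 15.4 ± 0.951 to 87.1 ± 5.24 CPM (log2 fold change 2.50 ± 0.13) and those of cebpb from 20.3 ± 1.2 to 71.5 ± 7.01 CPM (1.82 ± 0.12). The stress-induced transcription factor gene atf3 went from 7.19 ± 1.07 to 37.7 ± 3.8 CPM (2.39 ± 0.18). Of acute phase and complement genes, 11 of 47 rose and 0 fell (adjusted p = 7.15e-09, or adjusted p = 0.195 with an estimated correlation), fga going from 107 ± 10.7 to 471 ± 44.5 CPM (2.14 ± 0.11). Neutrophil genes went both ways, mmp9 up (2.29 ± 0.27) and mpx down (-1.67 ± 0.33), without passing (adjusted p = 0.41).

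Of all lysosomal genes, 14 of 148 rose and 3 fell with zymosan in triple mutants (14 and 3 adjusted over the list alone). The list did not pass camera (adjusted p = 0.436), and fry gave adjusted p = 0.0324. Levels of ctsla rose from 146 ± 15.1 to 271 ± 5.83 CPM (0.89 ± 0.10), and those of hexb fell from 61.9 ± 5.67 to 33.5 ± 1.82 CPM (-0.88 ± 0.11). The transporter gene spns1 rose as well (0.87 ± 0.15). The autophagy receptor gene sqstm1 rose from 17 ± 1.72 to 41.5 ± 5.89 CPM (1.29 ± 0.19), in a list that did not pass (adjusted p = 0.137). Of microglia and macrophage genes, 4 of 41 rose and 2 fell (4 and 2 adjusted over the list alone, adjusted p = 0.41).

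Clock genes rose in triple mutants too. Of these, 24 of 36 rose and 0 fell (27 and 0 adjusted over the list alone), and the list passed (adjusted p = 6.78e-47, or adjusted p = 3e-05 with an estimated correlation). Levels of per2 went from 10.1 ± 2 to 292 ± 8.82 CPM. Photoreceptor genes went down, and 18 of 36 fell and 4 rose (21 and 4 adjusted over the list alone, adjusted p = 1.4e-25, or adjusted p = 0.0167 with an estimated correlation). Levels of opn1sw1 went from 4344 ± 636 to 566 ± 25.4 CPM (log2 fold change -2.94 ± 0.16) and those of the red opsin gene opn1lw2 from 934 ± 99.2 to 222 ± 17.6 CPM (-2.07 ± 0.11). Of cell cycle genes, 16 of 40 fell and 1 rose (adjusted p = 1.03e-09, or adjusted p = 0.00118 with an estimated correlation). Among p53 targets, 7 of 17 rose and 0 fell (adjusted p = 7.06e-07, or adjusted p = 0.0138 with an estimated correlation), and among heat shock and oxidative stress genes, 20 of 44 rose and 5 fell (adjusted p = 7.06e-07, or adjusted p = 0.0314 with an estimated correlation). In lipid handling, 15 of 56 rose and 1 fell (adjusted p = 3.22e-06, or adjusted p = 0.025 with an estimated correlation), and in the integrated stress response, 15 of 47 rose and 1 fell (adjusted p = 1.7e-05, or adjusted p = 0.025 with an estimated correlation). Of interferon genes, 5 of 20 rose and 0 fell (adjusted p = 0.000859, or adjusted p = 0.0167 with an estimated correlation). Hepatocyte (8 of 33 up and 1 down, adjusted p = 7.06e-07, or adjusted p = 0.347 with an estimated correlation) and enterocyte genes (11 of 39 up and 0 down, adjusted p = 0.000176, or adjusted p = 0.347 with an estimated correlation) passed as higher. Erythrocyte (5 of 23 up and 0 down, adjusted p = 0.0357, or adjusted p = 0.347 with an estimated correlation), lens (5 of 38 up and 0 down, adjusted p = 6.9e-05, or adjusted p = 0.394 with an estimated correlation) and cholesterol synthesis genes (10 of 33 up and 0 down, adjusted p = 0.000428, or adjusted p = 0.0999 with an estimated correlation) did likewise.

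In triple mutants 2437 genes changed with zymosan, 1452 up and 985 down. Within the same limits, the largest increases were in cyp1a (5.57 ± 0.56), lonrf1l (4.99 ± 0.23), per2 (4.85 ± 0.42), the vitamin D catabolism gene cyp24a1 (4.09 ± 0.19) and nfil3-6 (3.90 ± 0.18). The largest decreases within them were in the opsin gene opn6b (-4.36 ± 0.31), serpinh1b (-4.21 ± 0.33), rx2 (-3.04 ± 0.29) and the opsin kinase gene grk1b (-2.96 ± 0.18). The fifth was opn1sw2 (-2.95 ± 0.16), which lies beside tfe3b on chromosome 11 (25459697 to 25475403). Both genotypes raised 837 genes, where independent lists would share 88.1, and lowered 410, where independent lists would share 37.7. Opposite calls were made for 1 gene. The responses correlated across genes (Pearson r = 0.536, Spearman rho = 0.524).

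**Figure D4:**
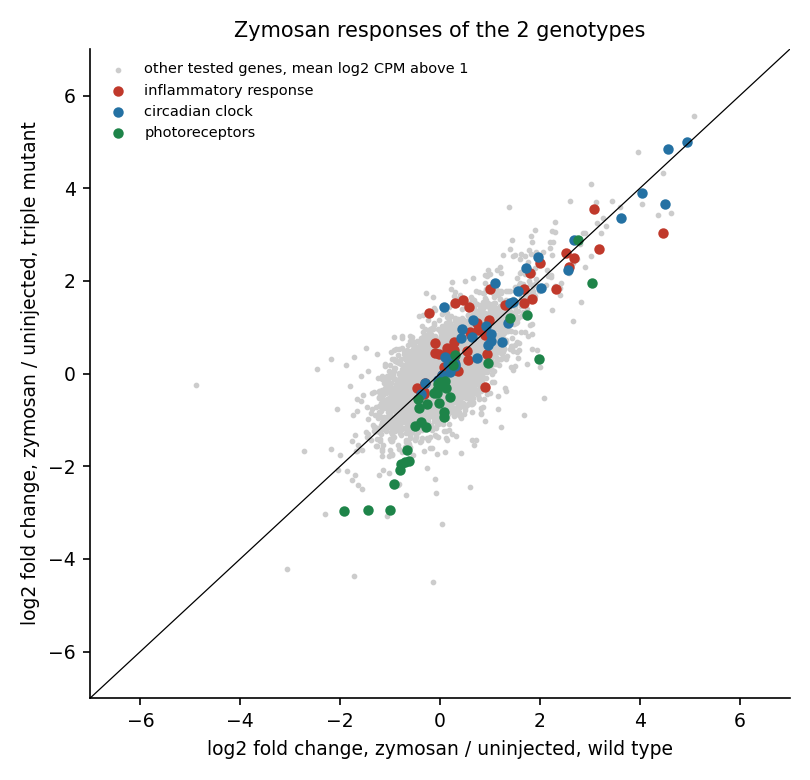
Log2 fold change with zymosan in wild type (x axis) and in triple mutants (y axis), a point per gene with mean log2 CPM above 1, with inflammatory genes in red, clock genes in blue, photoreceptor genes in green, others in grey and a line of equal response. Inflammatory genes lie near the line (socs3b at 2.68 and 2.50) or off it (junbb at 0.29 and 1.52), and most photoreceptor genes lie below it (opn1sw2 at -1.44 and -2.95).

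Whether the response itself depended on genotype was tested with the interaction of zymosan and the triple mutation. The response of lysosomal genes did not differ detectably, with 0 of 148 passing in edgeR (0 and 1 adjusted over the list alone, camera adjusted p = 0.794). Over all genes 1093 had an unadjusted p under 0.05 in this test and 27 passed. The member closest to the threshold was the v-ATPase gene atp6v1c1b (log2 difference -1.63 ± 0.34, adjusted p = 0.0506). Hydrolases (adjusted p = 0.52), autophagy genes (adjusted p = 0.819) and clock genes (adjusted p = 0.76) gave no difference, nor did microglia and macrophage genes (adjusted p = 0.691). Inflammatory genes did not differ in a common direction as a list (adjusted p = 0.352), but fry's test of changes in either direction gave adjusted p = 1.67e-07. That fry test does not compare members with other genes. In uninjected triple mutants against wild type it also passed autophagy genes (adjusted p = 0.0042), of which 1 of 56 had changed. In edgeR 2 members differed (4 and 1 adjusted over the list alone). The AP-1 gene junbb went from 25.7 ± 2.29 to 31.4 ± 4.71 CPM in wild type and from 15.2 ± 1.83 to 43.6 ± 6.23 CPM in triple mutants (1.22 ± 0.20, adjusted p = 0.00519). Its partner fosab differed likewise (1.13 ± 0.19, adjusted p = 0.00946). Both started lower in the mutants.

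In camera's test of a common direction, the photoreceptor list differed most. Of its 36 members, 10 responded more negatively in triple mutants and 0 more positively (18 and 0 adjusted over the list alone, camera adjusted p = 2.1e-46, or adjusted p = 0.0118 with an estimated correlation). The log2 difference was -1.94 ± 0.21 for opn1sw1 (adjusted p = 9.02e-05) and -1.27 ± 0.15 for opn1lw2 (adjusted p = 0.000125). It was -1.52 ± 0.21 for opn1sw2 (adjusted p = 0.00189) and -1.46 ± 0.22 for the green opsin gene opn1mw1 (adjusted p = 0.00305). Tandem copies of opsin genes can share reads. Acute phase genes passed toward a larger rise in mutants (0 of 47 single genes, 1 and 0 adjusted over the list alone, adjusted p = 0.0121, or adjusted p = 0.877 with an estimated correlation). Exocrine pancreas genes passed toward a larger fall (0 of 21 single genes, adjusted p = 0.000122, or adjusted p = 0.877 with an estimated correlation).

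Across all genes 27 differed in their response, 6 more positively and 21 more negatively in triple mutants. This count was not stable, at 54 (17 more positive) with DESeq2 and 77 (30) with no filter on low counts. It was 50 (17) without wild-type zymosan replicate 3, 17 (2) without triple-mutant zymosan replicate 1 and 16 (2) without wild-type uninjected replicate 1. Within the same limits on symbol and mean CPM, the largest positive differences beside junbb and fosab were in selenoj (1.23 ± 0.22), hebp2 (1.13 ± 0.23) and crtac1a (1.06 ± 0.21). Beside opn1sw1, the largest negative ones were in opn6b (-2.64 ± 0.40), the prion protein gene prnpa (-1.67 ± 0.23), cyp2n13 (-1.58 ± 0.25) and fam46ab (-1.57 ± 0.23). Simulated 2-fold interactions were recovered for 37% of genes and 4-fold ones for 76%, so many moderate differences would be missed.

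The rraga mutants were compared with uninjected wild type. Lysosomal genes were higher in them. Of these, 61 of 148 were higher and 4 lower (71 and 10 adjusted over the list alone), and the list passed (camera, adjusted p = 7.93e-16, or adjusted p = 0.000795 with an estimated correlation). Of the hydrolases, 39 of 68 were higher and 2 lower (41 and 3 adjusted over the list alone, adjusted p = 1.68e-20, or adjusted p = 0.000122 with an estimated correlation). The cathepsin gene ctsc stood at 65.3 ± 7.24 against 25 ± 0.757 CPM (log2 fold change 1.38 ± 0.11) and ctsz at 89.3 ± 1.54 against 38.2 ± 4.76 CPM (1.22 ± 0.11). Levels of ctsd were 130 ± 2.27 against 58.2 ± 6.06 CPM (1.16 ± 0.10) and those of ctsla 440 ± 32.4 against 227 ± 10.7 CPM (0.96 ± 0.10). The cathepsin B gene ctsba was higher too, at 171 ± 59.7 against 50.4 ± 8.8 CPM (1.76 ± 0.20).

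**Figure D5:**
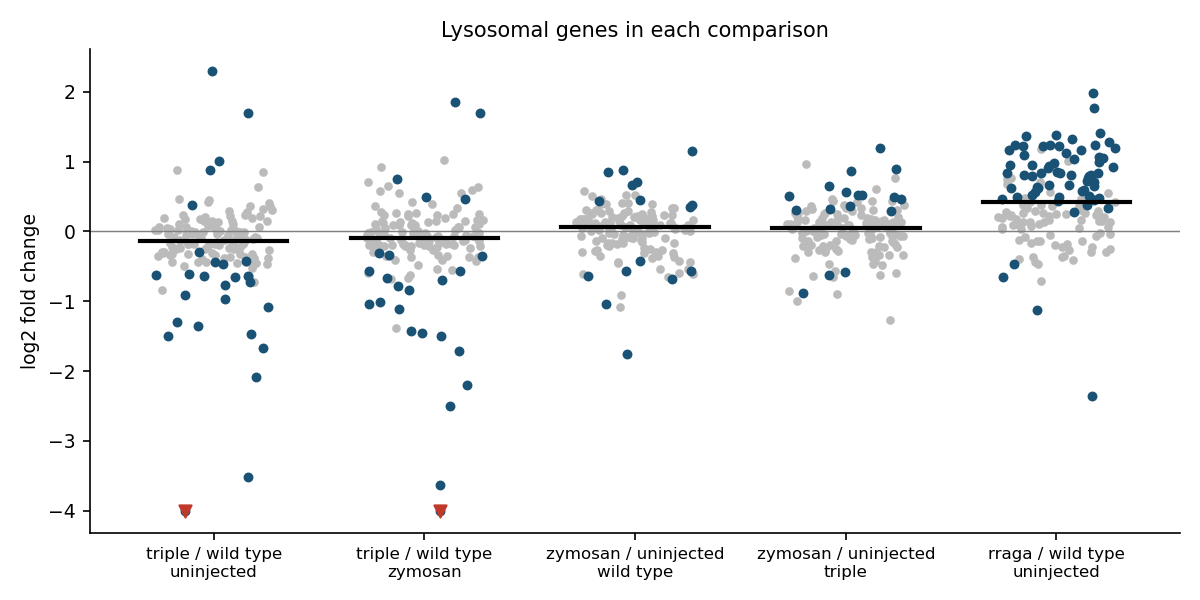
Log2 fold change (y axis) of 148 lysosomal genes in 5 comparisons (x axis), a point per gene, blue where it changed and grey elsewhere, with a black line at the median and a red triangle at -4 for ctsba, which had 0 counts in triple mutants. Medians are -0.13 and -0.10 for triple mutants without and with zymosan, 0.07 and 0.05 for zymosan in wild type and triple mutants, and 0.41 for rraga mutants.

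Lysosomal membrane genes were higher in rraga mutants, where 12 of 54 were higher and 2 lower (17 and 4 adjusted over the list alone, adjusted p = 0.000373, or adjusted p = 0.0201 with an estimated correlation). The cholesterol carrier gene npc2 was among them, at 72.5 ± 2.42 against 47.2 ± 0.809 CPM (0.62 ± 0.11). Of v-ATPase genes, 10 of 26 were higher and 0 lower (12 and 3 adjusted over the list alone, adjusted p = 0.000291, or adjusted p = 0.159 with an estimated correlation), with atp6v0a1a at 0.84 ± 0.10 and tcirg1b at 1.23 ± 0.17. Of autophagy genes, 9 of 56 were higher and 1 lower (11 and 1 adjusted over the list alone, adjusted p = 0.027, or adjusted p = 0.103 with an estimated correlation), including the receptor genes calcoco1b (2.21 ± 0.25) and sqstm1 (1.22 ± 0.20). In the Rag, Ragulator and mTORC1 pathway, 6 of 39 were higher and 2 lower, without passing as a list (adjusted p = 0.0588). There fnip1, for a folliculin partner, was higher (0.77 ± 0.12) and the translation inhibitor gene eif4ebp1 lower (-1.19 ± 0.19).

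Of microglia and macrophage genes, 6 of 41 were higher and 2 lower in rraga mutants (7 and 2 adjusted over the list alone). The list passed (adjusted p = 0.0472, or adjusted p = 0.104 with an estimated correlation), but not without the members that are also lysosomal (adjusted p = 0.122). Levels of apoeb were 422 ± 11.7 against 242 ± 8.29 CPM (0.80 ± 0.09) and those of ctsk 43.2 ± 5.47 against 18.9 ± 1.92 CPM (1.19 ± 0.17). Myelin genes were lower, and 10 of 26 were lower and 2 higher (11 and 2 adjusted over the list alone, adjusted p = 2.71e-09, or adjusted p = 0.000824 with an estimated correlation). The proteolipid gene plp1b stood at 3.01 ± 1.13 against 20.1 ± 2.46 CPM (-2.73 ± 0.21) and the claudin gene cldnk at 5.45 ± 0.99 against 20.4 ± 1.89 CPM (-1.90 ± 0.18). The myelin protein genes mag (-1.10 ± 0.12) and mbpa (-0.94 ± 0.10) were lower as well. Of neuronal genes, 18 of 36 were lower and 0 higher (22 and 0 adjusted over the list alone, adjusted p = 8.35e-10, or adjusted p = 0.031 with an estimated correlation). The synaptic vesicle gene vamp2 (-1.08 ± 0.12) and the glutamate transporter gene slc17a6b (-0.84 ± 0.12) led them.

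Erythrocyte genes were higher in rraga mutants (12 of 23 higher and 0 lower, adjusted p = 7.13e-10, or adjusted p = 0.0178 with an estimated correlation), with the embryonic globin gene hbae3 at 378 ± 67.2 against 140 ± 7.63 CPM (1.43 ± 0.18). Lipid handling genes were higher (18 of 56 higher and 2 lower, adjusted p = 2.4e-06, or adjusted p = 0.0265 with an estimated correlation) and cell cycle genes lower (13 of 40 lower and 1 higher, adjusted p = 0.000397, or adjusted p = 0.0265 with an estimated correlation). Lens genes (19 of 38 lower and 1 higher, adjusted p = 1.08e-09, or adjusted p = 0.159 with an estimated correlation) and ribosomal proteins (12 of 80 lower and 2 higher, adjusted p = 1.69e-06, or adjusted p = 0.463 with an estimated correlation) passed as lower. So did photoreceptors (16 of 36 lower and 5 higher, adjusted p = 0.000398, or adjusted p = 0.318 with an estimated correlation) and p53 targets (3 of 17 lower and 1 higher, adjusted p = 0.0472, or adjusted p = 0.222 with an estimated correlation). Enterocyte (15 of 39 higher and 0 lower, adjusted p = 1.16e-06, or adjusted p = 0.159 with an estimated correlation) and acute phase genes (13 of 47 higher and 2 lower, adjusted p = 1.22e-05, or adjusted p = 0.242 with an estimated correlation) passed as higher. Heat shock and oxidative stress (15 of 44 higher and 5 lower, adjusted p = 0.000299, or adjusted p = 0.106 with an estimated correlation) and neutrophil genes (6 of 30 higher and 1 lower, adjusted p = 0.00808, or adjusted p = 0.103 with an estimated correlation) did as well. Clock genes passed as higher (13 of 36 higher and 7 lower, adjusted p = 0.027, or adjusted p = 0.243 with an estimated correlation, median log2 fold change 0.05), as did pigment cell genes (9 of 32 higher and 3 lower, adjusted p = 0.0182, or adjusted p = 0.159 with an estimated correlation). Endoplasmic reticulum chaperones (4 of 28 higher and 0 lower, adjusted p = 0.0191, or adjusted p = 0.418 with an estimated correlation) and hepatocyte genes (6 of 33 higher and 1 lower, adjusted p = 0.0266, or adjusted p = 0.57 with an estimated correlation) were higher. Exocrine pancreas genes passed too (3 of 21 higher and 1 lower, adjusted p = 0.0115, or adjusted p = 0.463 with an estimated correlation). Inflammatory genes did not pass (adjusted p = 0.698).

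In rraga mutants 2659 genes changed, 1440 higher and 1219 lower. Within the same limits, the largest increases were in mipa (log2 fold change 6.33 ± 0.23), its chromosome 23 neighbour ptges3a (6.31 ± 0.29), cyp1a (4.95 ± 0.54), ldb2b (4.51 ± 0.54) and cxcl12b (4.39 ± 0.41). Among these, cyp1a varied widely, at 597 ± 464 against 19.4 ± 2.09 CPM. The largest decreases within them lay on chromosome 14, as rraga does. The thymosin gene tmsb1 (12066695 to 12071679) had 3 counts against 3375 (a ratio of 1160, counting interval 396 to 5610). The histone deacetylase gene hdac3 (12178915 to 12205865) had 1 against 509 (524, 93.5 to 20700). The glutamate receptor gene gria3b (-6.07 ± 0.65), hnrnpa0l (ENSDARG00000036161, -5.72 ± 0.36) and prps1b (-5.03 ± 0.42) followed. Between 10 and 15 Mb of chromosome 14, 13 of 52 tested genes were over 4-fold lower. Without chromosome 14, 2487 genes changed.

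Set directly against triple mutants without zymosan, rraga mutants had higher lysosomal transcripts. Of all lysosomal genes, 76 of 148 were higher and 5 lower (82 and 9 adjusted over the list alone), and the list passed (camera, adjusted p = 1.97e-18, or adjusted p = 0.000394 with an estimated correlation). Of hydrolases, 41 of 68 were higher and 0 lower (43 and 0 adjusted over the list alone, adjusted p = 4.46e-28, or adjusted p = 3.45e-05 with an estimated correlation). Counts of ctsba were 7054 against 0, at least 2590-fold higher. Levels of ctsa were 54.6 ± 3.75 against 12.8 ± 0.696 CPM (log2 fold change 2.09 ± 0.13), and ctsla (1.59 ± 0.10) and ctsc (1.72 ± 0.11) were higher as well. Lysosomal membrane genes were higher (adjusted p = 0.0016, or adjusted p = 0.0275 with an estimated correlation), and so were microglia and macrophage genes (adjusted p = 0.00218, or adjusted p = 0.0275 with an estimated correlation). The latter were led by ctsk (2.66 ± 0.18), apoeb (1.25 ± 0.10) and grn1 (1.77 ± 0.32).

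Lipid handling genes were higher in rraga than in triple mutants (29 of 56 higher and 2 lower, adjusted p = 1.71e-08, or adjusted p = 0.0161 with an estimated correlation). Myelin (10 of 26 lower and 1 higher, adjusted p = 3.38e-05, or adjusted p = 0.00966 with an estimated correlation) and neuronal genes (20 of 36 lower and 0 higher, adjusted p = 1.35e-08, or adjusted p = 0.0423 with an estimated correlation) were lower, and so were cell cycle genes (15 of 40 lower and 3 higher, adjusted p = 0.000738, or adjusted p = 0.0275 with an estimated correlation). In total 4831 genes changed, 2645 higher and 2186 lower. Within the same limits, the largest increases after ctsba were in actc1c (2580 counts against 2, a ratio of 1420, counting interval 393 to 11700) and hacd3 (430 against 1, 474, 84.6 to 18800). Then came grm2b (668 against 2, 368, 102 to 3050) and ces2 (8.05 ± 0.39), in the order of fitted fold changes. The count ratio of shisa4 (488 against 2, 269, 74.1 to 2230) was of similar size to the fold change of ces2. The largest decreases within them were in tmsb1 (3 against 1397, 422, 144 to 2050) and hdac3 (1 against 128, 116, 20.5 to 4620). Those in gngt2a (-6.06 ± 0.40), lta4h (-5.95 ± 0.35) and hnrnpa0l (-5.08 ± 0.36) followed.

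Over all genes the effects of both mutant genotypes, each against the same 3 uninjected wild-type libraries, correlated with r = 0.293 (Spearman rho = 0.222). Unchanged groups simulated against shared controls gave a mean r of 0.509 in 20 simulations, with a mean covariance of 0.0579 against 0.185 observed. Higher in both were 196 genes (56.5 for independent lists) and lower in both 175 (71.2). The simulated groups shared 0 genes, but called at most 1 gene per simulation, so that value says nothing on these counts. Another 106 were lower in triple and higher in rraga mutants, and 49 the reverse. Part of the excess over independent lists may come from the shared controls, whose 3 libraries were not split because a part would hold 1 library. Among the 5 largest named increases in rraga mutants, mipa, ptges3a, ldb2b and cxcl12b, but not cyp1a, recurred among the 5 largest in zymosan-injected triple mutants. That comparison uses wild-type libraries that the rraga comparison does not. Both sets are wild type, however, so the recurrence cannot tell a higher level in the mutants from a lower one in the wild-type fish. Why these genes were higher in both mutant genotypes was not tested.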

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

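The tests of the 3 patterns weighed here were chosen after results were seen, whereas the comparison with other ways of grouping the samples was planned before. A difference between groups marked 27 genes, whose response to zymosan was not the same in wild type and triple mutants, and 3 lists. The named genes with more positive responses in mutants were selenoj (log2 difference 1.23), junbb (1.22), fosab (1.13), hebp2 (1.13) and crtac1a (1.06). Those with more negative responses were opn6b (-2.64), opn1sw1 (-1.94), prnpa (-1.67), cyp2n13 (-1.58) and fam46ab (-1.57). The lists were photoreceptors (camera, adjusted p = 2.1e-46, or adjusted p = 0.0118 with an estimated correlation), exocrine pancreas (adjusted p = 0.000122) and acute phase and complement (adjusted p = 0.0121). The last 2 lists had 0 single members that passed and each gave adjusted p = 0.877 with an estimated correlation.

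For each comparison of 2 groups, 10 divisions of its 6 libraries into equal parts exist, and 1 of the 10, the real one, called as many genes as the real one did. The other divisions called at most 8 genes (zymosan in wild type, against 1881). With 10 divisions the smallest possible share is 0.1, so grouping by chance cannot be ruled out by this test alone. For the interaction, 4 of 100 divisions, the real one included, called at least 27 genes, and the largest called 451. These divisions exchanged genotype labels within each treatment. The one that called 451 genes exchanged 3 libraries per genotype without zymosan and 1 with it, so that differences between the genotypes entered the contrast. In divisions that mix the genotypes, these differences also enter the spread between libraries. The 4 of 100 therefore cannot decide whether the 27 genes arose by chance.

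Large differences between the genotypes sat side by side on chromosomes. Of the genes that changed over 4-fold in uninjected triple mutants, 63.2% had another within 0.5 Mb, against a mean of 30.7% after shuffling, which is consistent with chromosome segments that differ between the fish lines. Activation by Tfeb and Tfe3 that rises without RagA was examined for the 136 genes over 4-fold lower under zymosan in the dense windows. These were chosen on libraries that the rraga comparison does not use. Of the 136, 2.2% were higher in rraga mutants, against 7.6% of all tested genes (one-sided Fisher p = 0.00652). Their median log2 fold change there was -0.11 (quartiles -0.48 to 0.27), so most did not rise. That p-value treats the genes as independent, although they were picked as neighbours in 21 windows, so no conclusion is drawn from it. A gene that needs these factors only for its level in wild type need not rise in rraga mutants, so the test cannot exclude loss of such activation. Zymosan itself gave no such clustering (15.5% in wild type, with 25.4% the highest of the shuffles). Without reads it stays open whether variants in those segments stop reads from being counted or the transcripts are absent.

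Clock genes were higher in both zymosan groups. Of 7 genes of light-driven and excision DNA repair outside the clock list, 4 were higher with zymosan in wild type, among them ddb2 (4.04 ± 0.53). Lower was 1, xpa (-1.01 ± 0.31, adjusted p = 0.039). The count passed a bound of 50% of the list, which was set after results were seen. It would follow from light exposure or a time of collection that differed from that of uninjected wild type. However, ddb2 is also in the p53 list, so its rise cannot tell these from the rise of p53 targets. Against the same uninjected wild type, 4 of the 7 were higher in rraga mutants and 0 in uninjected triple mutants. Inflammatory signalling remains a possible contributor to the rise of the 22 clock genes higher with zymosan in wild type, since no injected group with known matched light and time exists.

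The response of photoreceptor genes to zymosan was more negative in triple mutants than in wild type. A smaller share of eye tissue in the triple-mutant zymosan larvae is argued against for this response by the lens list, whose median log2 difference of the responses was 0.05, against -0.66 for photoreceptors. In the direct comparison of the zymosan groups the lens list was lower too (median -0.43, quartiles -0.53 to -0.34, against -0.90 for photoreceptors, whose call there gave adjusted p = 0.0743 with an estimated correlation), so a smaller share of eye tissue stays open there. A single library as the source is argued against, since with each of the 12 libraries left out the adjusted p at the estimated correlation was at most 0.0352, and the median log2 difference lay between -0.73 and -0.57 with an upper quartile of at most -0.14. A different time of collection of the triple-mutant zymosan larvae could not be settled, as 7 of 36 clock genes changed between the zymosan groups (19.4% against 11.9% of all tested genes, one-sided Fisher p = 0.127).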

How the results depend on the processing

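The alternatives without dense windows, without nearly absent genes and with libraries left out at an estimated correlation are tests chosen after results were seen. In 6 of the 7 comparisons the count of changed genes stayed within 1.5-fold under every alternative, from DESeq2 and other filters to a replicate block and each library left out. The interaction gave 27 genes, but 54 with DESeq2, 77 without a filter on low counts, 16 without wild-type uninjected replicate 1, 17 without triple-mutant zymosan replicate 1 and 50 without wild-type zymosan replicate 3, and the cause was not tested. A replicate block left 1694 genes for uninjected triple mutants against wild type and 20 for the interaction. Same-number libraries did not pair (mean correlation -0.017). Lysosomal genes as a list kept their calls in rraga mutants (leaving libraries out, adjusted p between 1e-16 and 2.86e-12), and inflammatory genes kept theirs with zymosan in wild type (3.16e-23 to 3.03e-18) and in triple mutants (1.31e-25 to 2.85e-21). With an estimated correlation (0.019 in uninjected triple mutants, against the preset of 0.01), the lysosomal list lost its call there (0.386) and under zymosan (0.471). Before adjustment over the 33 lists, camera gave p = 0.000849 in uninjected triple mutants at the preset and p = 0.0234 at the estimated correlation. The call there was thus lost with the adjustment. How far the higher correlation accounts for the larger p was not tested. Under zymosan the list also lost its call without its nearly absent member (0.0679) and without triple-mutant zymosan replicate 2 (0.0704), within a range that began at 0.00968. For zymosan in triple mutants fry called it (0.0324) where camera did not. Its interaction stayed without a call (0.544 to 0.993) and changed sign in part of these fits. Of the effects of single targeted genes that had not passed, several changed sign with a library left out: tfe3a ran from -0.23 to 0.36 in the interaction and from -0.05 to 0.43 in rraga mutants, and tfeb from -0.24 to 0.15 in uninjected triple mutants (0 with a replicate block), from -0.32 to 0.06 with zymosan in wild type and from -0.02 to 0.36 between rraga and triple mutants. For tfe3b the range was -2.18 to 1.22 in the interaction and -1.42 to 1.99 with zymosan in triple mutants, where 12 of 13 counts come from replicate 3. The correlation of genotype effects was 0.904 among called genes alone and 0.71 to 0.743 with a library left out, and that of zymosan responses 0.803 and 0.434 to 0.49. Both correlations were lower whichever library was left out, and each of these fits held more genes (19328 to 19399) than the main fit (19006). Whether the added genes cause the lower values was not tested. Of 748 other results on genes, 109 lost their call under some alternative and 13 alternatives of 9052 reversed a sign. Of 85 other list results, 56 lost their call under some alternative, and 0 reversed. At this depth, simulated 2-fold changes were recovered for 59% of genes between uninjected triple mutants and wild type.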

Other observations

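The lists below were fixed before, and no further tests were chosen after results were seen. Set against triple mutants, rraga mutants also differed in lists that the report leaves out, at the preset correlation but not with an estimated one. Of skeletal muscle genes, 16 of 45 were higher and 4 lower (camera, adjusted p = 0.00132, or adjusted p = 0.44 with an estimated correlation), and of mitochondrially encoded genes, 10 of 13 were higher and 0 lower (adjusted p = 0.0016, or adjusted p = 0.428 with an estimated correlation). Of endoplasmic reticulum chaperones, 11 of 28 were higher and 0 lower (adjusted p = 0.0019, or adjusted p = 0.344 with an estimated correlation), and of erythrocyte genes, 10 of 23 were higher and 1 lower (adjusted p = 0.00218, or adjusted p = 0.214 with an estimated correlation). Enterocyte genes were higher as well, and 22 of 39 were higher and 1 lower (adjusted p = 6.12e-07, or adjusted p = 0.214 with an estimated correlation).

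Stress genes went both ways in uninjected triple mutants. Of heat shock and oxidative stress genes, 7 of 44 were lower and 5 higher (adjusted p = 0.731). The heat shock genes hsp70l (1.71 ± 0.16) and hsp90aa1.1 (1.53 ± 0.22) were higher, although near-identical copies of such genes can share reads. The peroxiredoxin gene prdx1, which removes peroxides, was higher too (0.47 ± 0.09). Cholesterol synthesis did not pass as a list (adjusted p = 0.432), but hmgcra, for its rate-limiting enzyme, was higher (1.29 ± 0.16), as was cyp51 (0.91 ± 0.14).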
